A study of Mus musculus with 31 samples.

How the data were processed

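The series holds 31 bulk RNA-seq libraries of CD45.2+ immune cells sorted from orthotopic AT3-OVA mammary tumours of female C57BL/6 mice. AT3-OVA is a triple negative mouse mammary tumour line that carries ovalbumin. Tumours received local radiotherapy as 3x4Gy or 1x20Gy, or the matching anaesthesia without radiation (3x0Gy, 1x0Gy), and were taken on day 5 or day 13 after its completion. Per the labels, RNA of all libraries had an integrity number above 8.5. Sample codes in the labels differ between day 5 and day 13, so day and experiment are confounded and levels were not compared across days.

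The deposited values are counts, 1 table per library with 38406 gene symbols and 5 summary lines of the counting tool. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 1.5, HISAT2 2.0.4, HTSeq 0.9.1 and the builds GRCm38 and mm10. The gene annotation, the strand setting and any read filter are not stated. All values were whole numbers, and library totals differed, as unscaled counts do. Reads carried no molecular identifiers in these tables, so limits from counts cover counting error only. Gene positions came from GENCODE M21 (GRCm38), in which 34467 of the 38406 symbols and 106 of 106 genes looked up were found. RP23-81C12.3, a clone-named symbol with many counts, was not in it, and what it codes for is unknown here.

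Total gene counts ran from 2641229 to 7541144 per library. Replicate libraries differed by more than counting error, with a chi-square per degree of freedom between 3.67 and 69.3 for pairs within a group. The median standard error of a log2 fold change was 0.22 for 3x4Gy against 3x0Gy, 0.22 for 1x20Gy against 1x0Gy at day 5 and 0.19 at day 13.

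Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood fit and test, two-sided). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested. The standard error (SE) of an edgeR log2 fold change is its absolute value divided by the square root of its test's F statistic. It thus follows from the test and is not a separate estimate. The 20 day 5 libraries shared 1 fit with 4 groups, and the 11 day 13 libraries had a fit of their own. The comparison of the 1x20Gy responses on both days used all 31 libraries. CPM values in the text are scaled by TMM unless said otherwise, and log2 CPM per library used a prior count of 2. No replicate block was used, because title numbers run within each group and nothing in the labels pairs animals.

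There were 7 comparisons: 3x4Gy against 3x0Gy, 1x20Gy against 1x0Gy at day 5 and at day 13, the difference of the 3x4Gy and 1x20Gy responses at day 5, 3x4Gy against 1x20Gy directly, 3x0Gy against 1x0Gy, and the 1x20Gy response at day 13 against that at day 5. Tests, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The fits were tested on simulated data, drawn as negative binomial counts with the libraries' depths and each gene's estimated spread, with 100 genes changed 2-fold and 100 genes changed 4-fold. In the 3 comparisons of irradiated with mock groups, 62%, 65% and 67% of the 2-fold changes and 95%, 94% and 92% of the 4-fold changes were recovered. For the difference of the regimens' responses this was 31% and 83%, for 3x4Gy against 1x20Gy 67% and 88%, for the mock groups 49% and 88%, and for the difference between days 37% and 84%. False calls made up between 2.52% and 8.09% of the calls.

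The 34 gene lists hold 491 entries, of which 479 matched a symbol in the tables, 8 matched by an older symbol (Igj for Jchain, for example) and 4 did not match. They cover T cells, cytotoxic lymphocyte genes, T cell exhaustion and activation, regulatory T cells, NK cells, B cells, plasma cells, neutrophils, monocytes, macrophages, suppressive myeloid genes, lipid and phagocytosis genes of macrophages, type 1 and type 2 conventional, mature and plasmacytoid dendritic cells, and mast cells with basophils and eosinophils. Epithelial, fibroblast, endothelial, adipose and erythroid lists cover other cells of the tumour. The remaining lists hold p53 targets, type I interferon and interferon gamma responses, MHC class I and class II presentation, cell cycle, inflammatory cytokines, monocyte chemokines, checkpoint ligands and costimulation, hypoxia and glycolysis, immediate early and heat shock genes, and mitochondrially encoded genes. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, which asks whether the genes of a list move in 1 direction on balance, were alternatives. Some genes stand in several lists (Ctla4, Trem2 and Ccr2, for example).

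The rule for named genes took, among called genes with a mean of at least 5 CPM and an ordinary gene symbol, the 10 genes with the largest change in each direction for irradiated against mock and 5 for other comparisons. It added up to 4 members of each list by smallest p and a fixed panel. The text names a subset of the genes this rule gives, picked after their values were seen. Single values per library were compared by exact permutation tests of the difference of means, two-sided, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. With 6 against 4 libraries the 210 splits allow no p below 0.00476. Figures were drawn with matplotlib 3.10.9.

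Alternatives fixed beforehand were DESeq2 size factors, upper quartile scaling and plain library size in place of TMM, no filter and a filter of 50 counts, DESeq2 1.42.0, limma voom with sample weights and edgeR with robust estimation, other sets of libraries in the fit, counting without immunoglobulin and T cell receptor genes or without the genes of non-leukocyte and mitochondrial lists, a replicate block, an adjusted p below 0.01, a minimum absolute log2 fold change of 1, and leaving out each replicate in turn. Alternatives added after the data were seen were counting without RP23-81C12.3 and mitochondrial rRNA genes, the share of reads outside annotated genes as a covariate, the mean of the epithelial and fibroblast lists per library as a covariate, day 13 without mock libraries 1 and 2, and the mean in place of the median of the epithelial list per library at day 13. The ovalbumin transgene, splice forms and cell numbers per tumour were not analysed here.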

Results

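Immune cells carrying CD45.2, the pan-leukocyte marker used for the sort, were profiled by bulk RNA-seq from mouse mammary tumours after 2 radiotherapy regimens. At day 5 there were 6 libraries after 3x4Gy and 4 after its mock schedule 3x0Gy, and 6 after 1x20Gy and 4 after its mock 1x0Gy. At day 13 there were 7 libraries after 1x20Gy and 4 after 1x0Gy. Each library is 1 deposited table of gene counts. Mean totals were 4755034 ± 819101 gene counts after 3x4Gy (SD, n = 6) and 4240510 ± 1683611 after 3x0Gy (n = 4). They were 5011047 ± 470124 after 1x20Gy (n = 6) and 6214237 ± 889099 after 1x0Gy (n = 4) at day 5. At day 13 they were 3552614 ± 623187 after 1x20Gy (n = 7) and 3627961 ± 351795 after 1x0Gy (n = 4).

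Reads outside annotated genes took a larger mean share of the uniquely placed reads in each irradiated group than in its mock group. The means were 24.1 ± 2.9% after 3x4Gy (n = 6) against 16.1 ± 7.3% (n = 4; exact permutation p = 0.0143, adjusted 0.112 over 55 tests of library measures). After 1x20Gy they were 23.5 ± 4.5% (n = 6) against 16.9 ± 1.2% (n = 4; exact p = 0.0238, adjusted 0.164) at day 5 and 25.8 ± 3.7% (n = 7) against 20.4 ± 2.6% (n = 4; exact p = 0.0364, adjusted 0.167) at day 13. None of the 3 differences held after adjustment. Without 3x0Gy library 2 (5.66%) the 3x0Gy mean was 19.6 ± 2.7% (n = 3) and the difference fell from 8.04 to 4.57 percentage points (exact p = 0.0595). The clone-named gene RP23-81C12.3 took 22.4 ± 4.2% of the gene counts at day 13 after 1x20Gy (n = 7) and 9.25 ± 6.40% after 1x0Gy (n = 4; exact p = 0.00303, adjusted 0.0152 over 5 tests). At day 5 it took 6.50 ± 3.13% after 3x4Gy (n = 6) against 2.93 ± 2.08% (n = 4; exact p = 0.0905) and 10.5 ± 4.7% after 1x20Gy (n = 6) against 3.67 ± 1.68% (n = 4; exact p = 0.0381, adjusted 0.0952).

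**Figure D1:**
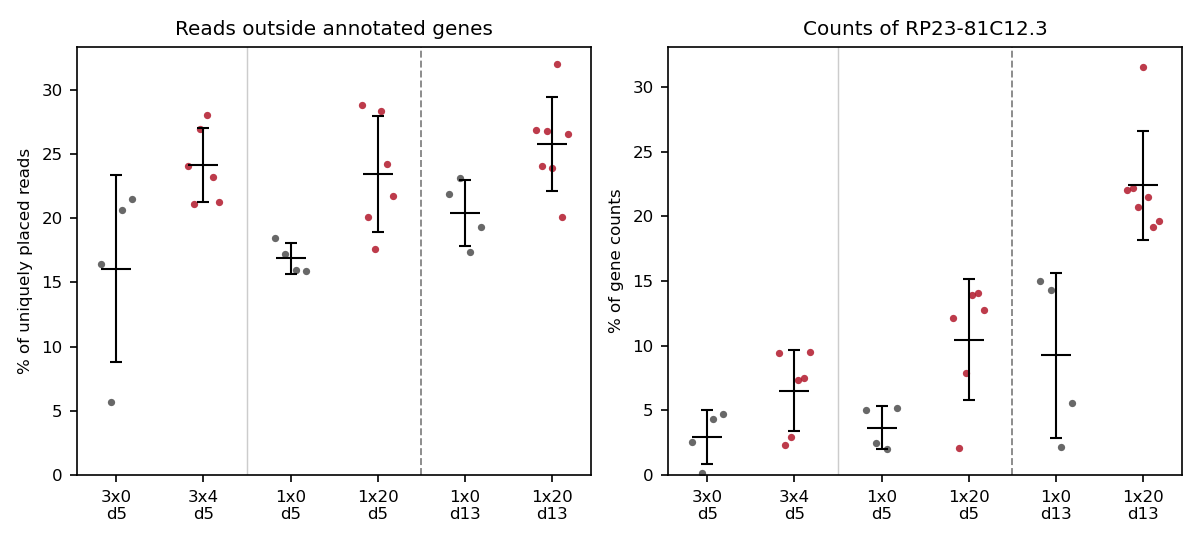
Left, reads outside annotated genes as a percentage of uniquely placed reads, and right, counts of RP23-81C12.3 as a percentage of gene counts, for each library (points), with mean and SD per group (bars); irradiated groups are red and mock groups grey. At day 13 the RP23-81C12.3 share averages 22.4% after 1x20Gy and 9.25% after 1x0Gy.

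The mock schedules were compared first, as the background for all that follows. Between 3x0Gy and 1x0Gy (n = 4 each) edgeR called 0 of 12021 genes, with 667 genes at an unadjusted p below 0.05 where 601 are expected by chance. DESeq2 called 1 gene and limma voom 0. Mast cell, basophil and eosinophil markers had a list median log2 fold change of 1.46 in favour of 3x0Gy with 0 of 8 members called (5 higher adjusted over the list alone; camera adjusted p = 9.3e-05, adjusted p = 0.32 with an estimated correlation). T cell markers had a median of 0.52 with 0 of 19 called (0 adjusted over the list alone; camera adjusted p = 0.00033, adjusted p = 0.66 with an estimated correlation). With its preset correlation, camera thus called 17 of 33 lists between groups of which none was irradiated, against 0 with an estimated correlation and 0 by fry. That number is the background for camera calls in the other comparisons.

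At day 5 after 3x4Gy, most fibroblast and matrix genes measured fell, and most regulatory T cell markers rose, as did Cdkn1a and Inhba. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, reached 839 ± 154 CPM (SD, n = 6) against 310 ± 98.8 CPM in mocks (n = 4), a log2 fold change of 1.44 (SE 0.19, adjusted p = 4.1e-05). Foxp3, the lineage factor of regulatory T cells, rose from 6.59 ± 3.34 to 22.2 ± 11.1 CPM (log2 fold change 1.81, SE 0.45, adjusted p = 0.011). Inhba, which encodes the activin A subunit, rose from 1.83 ± 1.06 to 19.9 ± 10.9 CPM (log2 fold change 3.36, SE 0.49, adjusted p = 0.00012). Mgp, matrix Gla protein, fell from 249 ± 140 to 4.86 ± 2.95 CPM (log2 fold change -5.70, SE 0.46, adjusted p = 2.1e-07).

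In all, 625 genes were higher and 852 lower of 12021 tested, and 178 of the higher and 562 of the lower changed at least 2-fold. On GRCm38, Cdkn1a lies on chromosome 17 (29090976 to 29100727, plus strand), Foxp3 on chromosome X (7573644 to 7595245, plus strand), Inhba on chromosome 13 (16011851 to 16031621, plus strand) and Mgp on chromosome 6 (136872435 to 136875823, minus strand). Among the largest increases were F10, coagulation factor X (log2 fold change 3.13, SE 0.43; chromosome 8, 13037308 to 13056676, plus strand), the glutathione-degrading enzyme Chac1 (2.86, SE 0.45), F7, coagulation factor VII (2.34, SE 0.62), the guanylate-binding protein Gbp2b (2.34, SE 0.49) and the matrix metalloproteinase Mmp19 (2.00, SE 0.37). Counts of Gbp2b and of the Ly6 family gene Ly6i (2.98, SE 0.60) can be shared with close paralogs. Among the largest decreases were the secreted Wnt inhibitor Wif1 (-5.72, SE 0.53; chromosome 10, 121033960 to 121100650, plus strand), the imprinted genes Peg3 (-4.72, SE 0.40) and H19 (-4.10, SE 0.53) and the matrix genes Smoc1 (-4.49, SE 0.49) and Postn (-4.22, SE 0.44). Dcpp3, a gene with close paralogs, had 0 counts in the 6 irradiated libraries and 240 in the 4 mock libraries. The mock mean of 13.9 ± 11.2 CPM, here by total counts (SD, n = 4), was 133 times a floor of 3 counts over the irradiated group. That mean varied widely between libraries, so the ratio is no firm limit.

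Of 9 measured regulatory T cell markers, 7 rose and 2 were not called (8 rose adjusted over the list alone), among them the high-affinity interleukin-2 receptor chain Il2ra (1.21, SE 0.24) and the inhibitory receptor Ctla4 (1.55, SE 0.42). The list median was 1.35 (camera adjusted p = 3.4e-05, adjusted p = 0.34 with an estimated correlation, fry adjusted p = 0.015). The call of Ctla4 ended without 3x0Gy library 1 (adjusted p = 0.0509) and without library 4 (adjusted p = 0.0504). T cell markers had 1 of 19 called as higher and 18 not called (0 adjusted over the list alone; median 0.42, camera adjusted p = 0.034, adjusted p = 0.70 with an estimated correlation). Cytotoxic lymphocyte genes had 1 of 18 called as higher (1 adjusted over the list alone; camera adjusted p = 1.0, median -0.17). Cd8a was at 92.7 ± 28.7 against 133 ± 60.5 CPM (adjusted p = 0.41), Gzmb, granzyme B, at 53 ± 17.3 against 61.4 ± 25.6 CPM (adjusted p = 0.74) and Ifng at 14.2 ± 6.3 against 16.3 ± 4.7 CPM (adjusted p = 0.81), and none of these was called.

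Among myeloid lists, 3 of 12 monocyte genes rose and 1 fell (5 and 2 adjusted over the list alone; median 0.64, camera adjusted p = 0.022, adjusted p = 0.42 with an estimated correlation). Ccr2, the receptor for monocyte chemoattractants, rose by 1.12 (SE 0.25), and F13a1, coagulation factor XIII A, fell by 1.14 (SE 0.34), a call that ended when 3x4Gy library 2 (adjusted p = 0.0561) or 4 (0.0609) or 3x0Gy library 2 (0.0685), 3 (0.0641) or 4 (0.0755) was left out. Mature dendritic cell genes had 4 of 12 higher and 0 lower (6 adjusted over the list alone), including the NF-kB subunit Relb (0.72, SE 0.15). The list median was 0.72 (camera adjusted p = 0.0028, adjusted p = 0.34 with an estimated correlation). Checkpoint and costimulation genes had 3 of 11 higher (3 higher and 1 lower adjusted over the list alone; median 0.54, camera adjusted p = 0.022, adjusted p = 0.35 with an estimated correlation), with Cd40 at 0.96 (SE 0.20). Inflammatory cytokine genes had 3 of 15 higher and 1 lower (6 and 1 adjusted over the list alone; median 0.51, camera adjusted p = 0.027, adjusted p = 0.59 with an estimated correlation). Ptgs2, cyclooxygenase 2, rose by 1.73 (SE 0.32), and by 2.32 without 3x0Gy library 4. In the list of lipid and phagocytosis genes of macrophages 3 of 14 fell (3 adjusted over the list alone; median -0.52, camera adjusted p = 0.022, adjusted p = 0.62 with an estimated correlation). They included the lipid receptor Trem2 (-1.73, SE 0.40) and the lysosomal protease Ctsd (-0.97, SE 0.24). Retnla, a gene of alternatively activated macrophages, fell by 3.08 (SE 0.66), and by 3.67 without 3x4Gy library 6.

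Of 20 p53 targets, 4 rose and 1 fell (4 and 2 adjusted over the list alone), including the apoptosis gene Bax (1.22, SE 0.21). The list was not called (median 0.15, camera adjusted p = 0.089, adjusted p = 0.34 with an estimated correlation). Cell cycle genes had 3 of 27 higher and 0 lower (4 adjusted over the list alone), with the proliferation marker Mki67 at 0.99 (SE 0.23). The list had a median of 0.29 (camera adjusted p = 0.0088, adjusted p = 0.49 with an estimated correlation). Of 14 immediate early and heat shock genes 4 fell (6 adjusted over the list alone, median -0.24, camera adjusted p = 0.031, adjusted p = 0.34 with an estimated correlation), led by the transcription factor Egr1 (-1.86, SE 0.23). Egr1 was at 662 ± 222 CPM in 3x0Gy and 330 ± 62.4 CPM in 1x0Gy (n = 4 each, log2 fold change 1.01, edgeR adjusted p = 0.80). The list mean was 8.11 ± 0.09 log2 CPM in 3x0Gy and 7.79 ± 0.10 in 1x0Gy, against 7.66 ± 0.28 after 3x4Gy and 7.60 ± 0.19 after 1x20Gy. Part of the fall thus lies between the mocks. Plasma cell genes had 5 of 10 lower (7 adjusted over the list alone; median -1.51, camera adjusted p = 0.0011, adjusted p = 0.33 with an estimated correlation). The immunoglobulin heavy chain gene Ighg2c fell by 4.00 (SE 0.75), and by 2.68 without 3x0Gy library 1. Ighg2b fell by 2.77 (SE 0.60), and by 2.17 without that library, and the joining chain gene Igj by 1.95 (SE 0.46). Between the mocks Ighg2c was at 156 ± 192 CPM in 3x0Gy and 26.6 ± 16.6 CPM in 1x0Gy (n = 4 each, log2 fold change 2.55, edgeR adjusted p = 0.84).

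Markers of other cells of the tumour moved as well. Fibroblast and matrix genes had 7 of 8 lower (8 adjusted over the list alone; median -2.33, camera adjusted p = 2e-09, adjusted p = 0.22 with an estimated correlation), including Col1a1 (-2.65, SE 0.51) and Sparc (-2.42, SE 0.42). Per library, the median of their log2 CPM was 1.75 ± 0.46 (n = 6) against 4.01 ± 0.76 in mocks (n = 4; exact permutation p = 0.00476, the smallest possible, adjusted 0.0238 over 25 tests). Epithelial and tumour cell markers had 5 of 15 lower (6 adjusted over the list alone), with Krt14 at -2.51 (SE 0.46) and Epcam at -1.61 (SE 0.39). Members had a median of -0.75 (camera adjusted p = 0.0006, adjusted p = 0.49 with an estimated correlation). Adipose and mammary gland genes had 1 of 3 lower (3 adjusted over the list alone; camera adjusted p = 0.0025, adjusted p = 0.22 with an estimated correlation). Both measured erythroid genes fell (both adjusted over the list alone), Hba-a2 by 2.16 (SE 0.32). Of 7 endothelial markers 2 rose (3 adjusted over the list alone; camera adjusted p = 0.05, median 0.52), including Pecam1 (1.22, SE 0.24), which leukocytes also express.

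The remaining lists were not called for 3x4Gy by camera. Counts of called members, higher then lower, were 1 and 0 of 12 exhaustion and activation genes, 1 and 2 of 12 NK cell markers, 1 and 0 of 9 B cell markers, 3 and 1 of 13 neutrophil genes, 1 and 2 of 19 macrophage genes and 0 and 1 of 13 suppressive myeloid genes. They were 1 and 0 of 11 type 1 and 2 and 0 of 8 type 2 conventional dendritic cell markers, 0 and 0 of 8 plasmacytoid dendritic cell markers and 1 and 0 of 8 mast cell, basophil and eosinophil markers. Type I interferon response genes had 0 and 1 of 26, interferon gamma response genes 2 and 0 of 18, MHC class I genes 1 and 0 of 15, MHC class II genes 2 and 0 of 10, monocyte chemokine genes 2 and 0 of 9, hypoxia and glycolysis genes 1 and 3 of 14 and mitochondrially encoded genes 0 and 2 of 11. The interferon-induced Gbp5 rose by 1.26 (SE 0.28), while Cxcl10 was at 198 ± 56.5 against 263 ± 114 CPM (adjusted p = 0.27). In the neutrophil list Hdc, histidine decarboxylase, rose by 1.68 (SE 0.33) and Lcn2, lipocalin 2, fell by 2.51 (SE 0.48). Egln3, a hypoxia-induced prolyl hydroxylase, fell by 2.15 (SE 0.30). The suppressive myeloid list had a median of 0.17 and a mean of -0.15, and the plasmacytoid list a median of 0.37 with a test pointing down.

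With the 3x4Gy and 3x0Gy libraries alone in the fit 702 genes were called, 698 of them among the 1477. Of 47 calls followed through this alternative 5 ended, Epcam among them, and by limma voom 5 of 48 ended, Trem2 among them. At an adjusted p below 0.01 there were 665. Scaling changed the split of the 3x4Gy calls, to 450 higher and 1110 lower with upper quartile scaling and 325 higher and 1084 lower by library size. With the mean of the epithelial and fibroblast lists per library as a covariate, 278 genes were called, 235 of them among the 1477. Of the 1477 genes 1474 kept their sign. In the 1242 calls that ended, fold changes had a median ratio of 0.813 (quartiles 0.58 and 0.992) to those without it and standard errors one of 1.29 (1.21 and 1.34). In all 1477 calls these ratios were 0.839 (0.617 and 1.02) and 1.29 (1.21 and 1.33). Ended calls are selected for a smaller estimate or a wider error, so their ratios alone do not show why they ended. Of the 48 followed calls 24 ended with this covariate. For Col1a1 the log2 fold change went from -2.65 (SE 0.51) to -1.36 (SE 0.53), and for Ctla4 from 1.55 (SE 0.42) to 1.45 (SE 0.52). Col1a1, Sparc, Krt14 and Epcam are members of the lists in this covariate, so a smaller estimate is in part built in for them. Of the genes named above, Cdkn1a, Bax, Foxp3, Il2ra, Inhba, F10, Mgp, Wif1, Relb, Mki67 and Egr1 kept their calls with it, while Ctla4, Hdc, Ccr2, F13a1, F7, Gbp2b, Cd40, Gbp5, Ptgs2, Pecam1, Retnla, Ctsd, Lcn2, Col1a1, Sparc, Krt14, Epcam and the immunoglobulin genes did not. With the share of reads outside annotated genes as a covariate, 667 genes were called, 601 of them among the 1477, and 11 of the 48 followed calls ended, among them Mki67, Trem2, Ccr2, Ctsd, Ctla4, F13a1 and Igj.

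**Figure D2:**
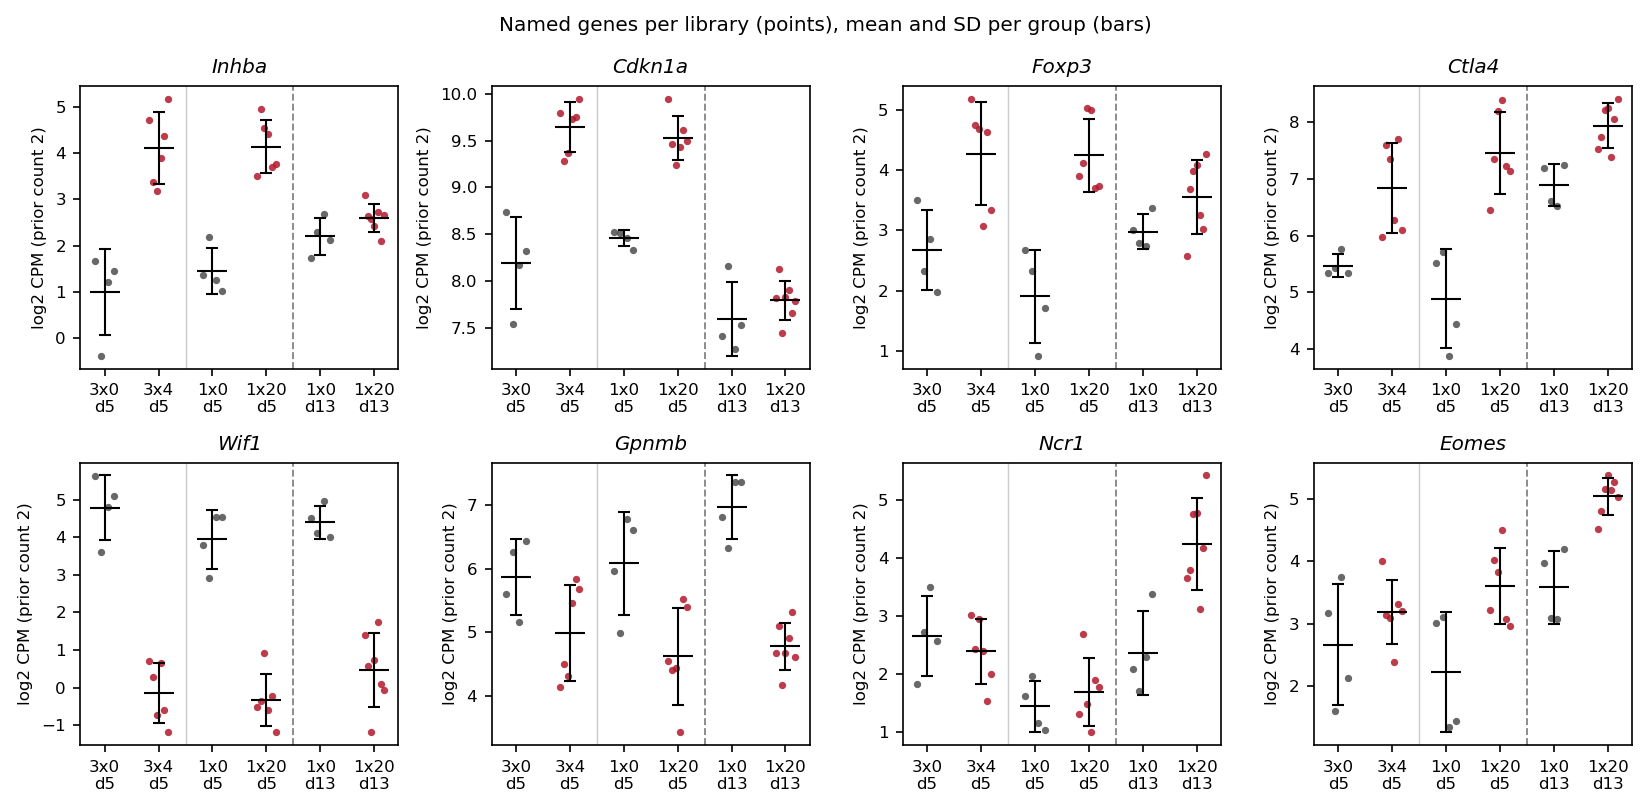
Expression of 8 genes in each library (points), as log2 CPM with a prior count of 2, with mean and SD per group (bars); irradiated groups are red and mock groups grey. Inhba, Cdkn1a, Foxp3 and Ctla4 are higher in both irradiated groups than in their mocks at day 5, with log2 fold changes of 3.36, 1.44, 1.81 and 1.55 after 3x4Gy and 2.93, 1.11, 2.44 and 2.57 after 1x20Gy, and Wif1 is lower in each irradiated group.

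At day 5 after 1x20Gy, members of the regulatory T cell, cell cycle, mast cell and inflammatory cytokine lists rose, and members of the epithelial and matrix lists fell. Ctla4 rose from 33.7 ± 18.5 CPM (SD, n = 4) to 201 ± 101 CPM (n = 6), a log2 fold change of 2.57 (SE 0.44, adjusted p = 0.00082). Foxp3 rose from 3.74 ± 1.98 to 20.7 ± 9.56 CPM (log2 fold change 2.44, SE 0.46, adjusted p = 0.0017). Cdkn1a rose from 357 ± 21.9 to 770 ± 132 CPM (log2 fold change 1.11, SE 0.19, adjusted p = 0.0008). Mgp fell from 100 ± 44.2 to 3.58 ± 2.40 CPM (log2 fold change -4.77, SE 0.46, adjusted p = 1.7e-06).

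Altogether 441 genes were higher and 587 lower of 12021, with 181 higher and 449 lower by at least 2-fold. Large increases were seen for Chac1 (3.84, SE 0.43), Inhba (2.93, SE 0.45), F10 (2.51, SE 0.39) and Klrg1, a receptor of differentiated lymphocytes (2.49, SE 0.42). The interleukin-36 gene Il1f9 had a log2 fold change of 5.61 (SE 1.28), and of 3.52 without 1x20Gy library 2, and was not called by DESeq2. Large decreases were seen for Wif1 (-5.03, SE 0.55; -5.93 without 1x20Gy library 3), Peg3 (-4.42, SE 0.41) and Sertad4 (-3.96, SE 0.36). CD45 itself, Ptprc, was at 893 ± 145 CPM (n = 6) against 823 ± 186 CPM (n = 4; edgeR adjusted p = 0.83).

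All 9 regulatory T cell markers had a positive log2 fold change, 7 were called (9 adjusted over the list alone) and the median was 1.74 (camera adjusted p = 2.6e-10, adjusted p = 0.11 with an estimated correlation, fry adjusted p = 0.0026). The costimulatory receptor Tnfrsf4 rose by 1.88 (SE 0.39). Of 19 T cell markers 6 rose and 13 were not called (10 rose adjusted over the list alone). The surface receptors Cd5 (1.67, SE 0.34) and Cd2 (1.5, SE 0.35) were among those that rose. In 3x0Gy Cd5 was 0.57 and Cd2 0.75 log2 higher than in 1x0Gy (n = 4 each, edgeR adjusted p = 0.84 for both). The list median was 0.89 (camera adjusted p = 6.5e-08, adjusted p = 0.37 with an estimated correlation). Cytotoxic lymphocyte genes had 0 of 18 called (0 adjusted over the list alone; median 0.34, camera adjusted p = 0.029, adjusted p = 0.69 with an estimated correlation). Cd8a was at 100 ± 43.4 against 87.4 ± 58.9 CPM (adjusted p = 0.83) and Gzmb at 51.3 ± 22.1 against 38.8 ± 19.9 CPM (adjusted p = 0.55). Cell cycle genes had 8 of 27 higher and 0 lower (16 adjusted over the list alone; median 0.54, camera adjusted p = 2.6e-10, adjusted p = 0.11 with an estimated correlation). The mitotic genes Ube2c (1.13, SE 0.19), Plk1 (1.04, SE 0.19) and Birc5 (0.88, SE 0.17) were among them. Of 20 p53 targets 5 rose (8 higher and 1 lower adjusted over the list alone; median 0.40, camera adjusted p = 0.0016, adjusted p = 0.055 with an estimated correlation), including the nuclease gene Aen (0.75, SE 0.17).

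Mast cell, basophil and eosinophil markers had 5 of 8 higher (6 adjusted over the list alone), with the mast cell proteases Cma1 (2.44, SE 0.51) and Mcpt4 (2.75, SE 0.52). The list had a median of 2.03 (camera adjusted p = 4.4e-06, adjusted p = 0.11 with an estimated correlation). Part of this gap is also seen between the mocks. The list mean was 1.25 ± 0.37 log2 CPM in 1x0Gy and 2.25 ± 0.73 in 3x0Gy, against 3.01 ± 0.32 after 1x20Gy. In 3x0Gy Cma1 was 1.80 and Mcpt4 1.78 log2 higher than in 1x0Gy (n = 4 each, edgeR adjusted p = 0.84 for both). Of 13 neutrophil genes 5 rose and 1 fell (8 and 1 adjusted over the list alone; median 2.12, camera adjusted p = 0.00018, adjusted p = 0.20 with an estimated correlation). Hdc rose by 2.13 (SE 0.33) and the receptor Trem1 by 1.11 (SE 0.26), and the member that fell was Lcn2 (-1.98, SE 0.49), a call that ended without 1x0Gy library 3 (adjusted p = 0.0532). Inflammatory cytokine genes had 6 of 15 higher (9 adjusted over the list alone), including the neutrophil chemokine Cxcl2 (1.59, SE 0.37), the interleukin-1 antagonist Il1rn (1.21, SE 0.27) and Ptgs2 (1.39, SE 0.31). Members had a median of 0.57 (camera adjusted p = 4.4e-06, adjusted p = 0.20 with an estimated correlation). Monocyte genes had 2 of 12 higher (6 adjusted over the list alone; median 0.86, camera adjusted p = 0.00037, adjusted p = 0.16 with an estimated correlation). Type 2 conventional dendritic cell markers had 3 of 8 higher (3 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.13 with an estimated correlation) and type 1 markers 2 of 11 (3 adjusted over the list alone; camera adjusted p = 0.029, adjusted p = 0.48 with an estimated correlation). Mature dendritic cell genes had 1 of 12 higher (2 adjusted over the list alone; camera adjusted p = 0.048, adjusted p = 0.48 with an estimated correlation).

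Macrophage genes had 1 of 19 higher and 1 lower (1 and 1 adjusted over the list alone; median -0.48, camera adjusted p = 0.031, adjusted p = 0.69 with an estimated correlation). Lipid and phagocytosis genes had 3 of 14 lower (6 adjusted over the list alone; median -0.46, camera adjusted p = 0.00091, adjusted p = 0.48 with an estimated correlation), with Ctsd at -1.30 (SE 0.24). The growth factor gene Tgfb1 fell by 0.96 (SE 0.18) and the interferon-induced Bst2, tetherin, by 1.01 (SE 0.20), while Cxcl10 was at 178 ± 38.2 against 183 ± 29.4 CPM (adjusted p = 0.95). Epithelial and tumour cell markers had 7 of 15 lower (9 adjusted over the list alone), including Krt14 (-3.03, SE 0.48) and Epcam (-1.80, SE 0.39). The list median was -1.67 (camera adjusted p = 4.9e-09, adjusted p = 0.20 with an estimated correlation). Fibroblast and matrix genes had 2 of 8 lower (4 adjusted over the list alone; median -1.25, camera adjusted p = 7.9e-05, adjusted p = 0.25 with an estimated correlation), Postn (-3.04, SE 0.43) and Sparc (-2.08, SE 0.41). Adipose and mammary gland genes had 1 of 3 lower (3 adjusted over the list alone; camera adjusted p = 0.0028, adjusted p = 0.11 with an estimated correlation). Both erythroid genes fell, Hba-a2 by 1.83 (SE 0.30). Per library, the median of the epithelial markers was 2.11 ± 0.82 log2 CPM (n = 6) against 3.46 ± 0.35 (n = 4; exact p = 0.0238, adjusted 0.0595).

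The 1x20Gy count fell to 582 genes without 1x0Gy library 3 and to 556 without library 4. Either omission ended 7 of the 45 followed calls. It was 1957 by limma voom, 625 with the stricter filter and 425 at an adjusted p below 0.01. Splits were 317 higher and 745 lower with upper quartile scaling and 210 higher and 947 lower by library size, which moved the median of all genes by -0.13. With the epithelial and fibroblast mean as a covariate 204 genes were called, 184 of them among the 1028. In the 844 calls that ended, fold changes had a median ratio of 0.758 (quartiles 0.488 and 1.03) and standard errors one of 1.29 (1.17 and 1.35). In all 1028 calls these ratios were 0.842 (0.527 and 1.1) and 1.29 (1.18 and 1.35). Of the 45 followed calls 22 ended with this covariate. Foxp3, Ctla4, Tnfrsf4, Cd5, Cd2, Klrg1, Hdc, Cdkn1a, Aen, Ube2c, Plk1, Birc5, Chac1, Inhba, F10, Mgp and Wif1 kept their calls with it, and Cma1, Mcpt4, Trem1, Cxcl2, Il1rn, Ptgs2, Tgfb1, Ctsd, Postn, Sparc, Krt14, Epcam, Hba-a2, Il1f9 and Lcn2 did not. Postn, Sparc, Krt14 and Epcam are members of the lists in this covariate, so a smaller estimate is in part built in for them. With the share of reads outside annotated genes as a covariate 737 genes were called, 591 of them among the 1028, and 8 of the 45 followed calls ended, among them Lcn2 and Ptgs2.

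**Figure D3:**
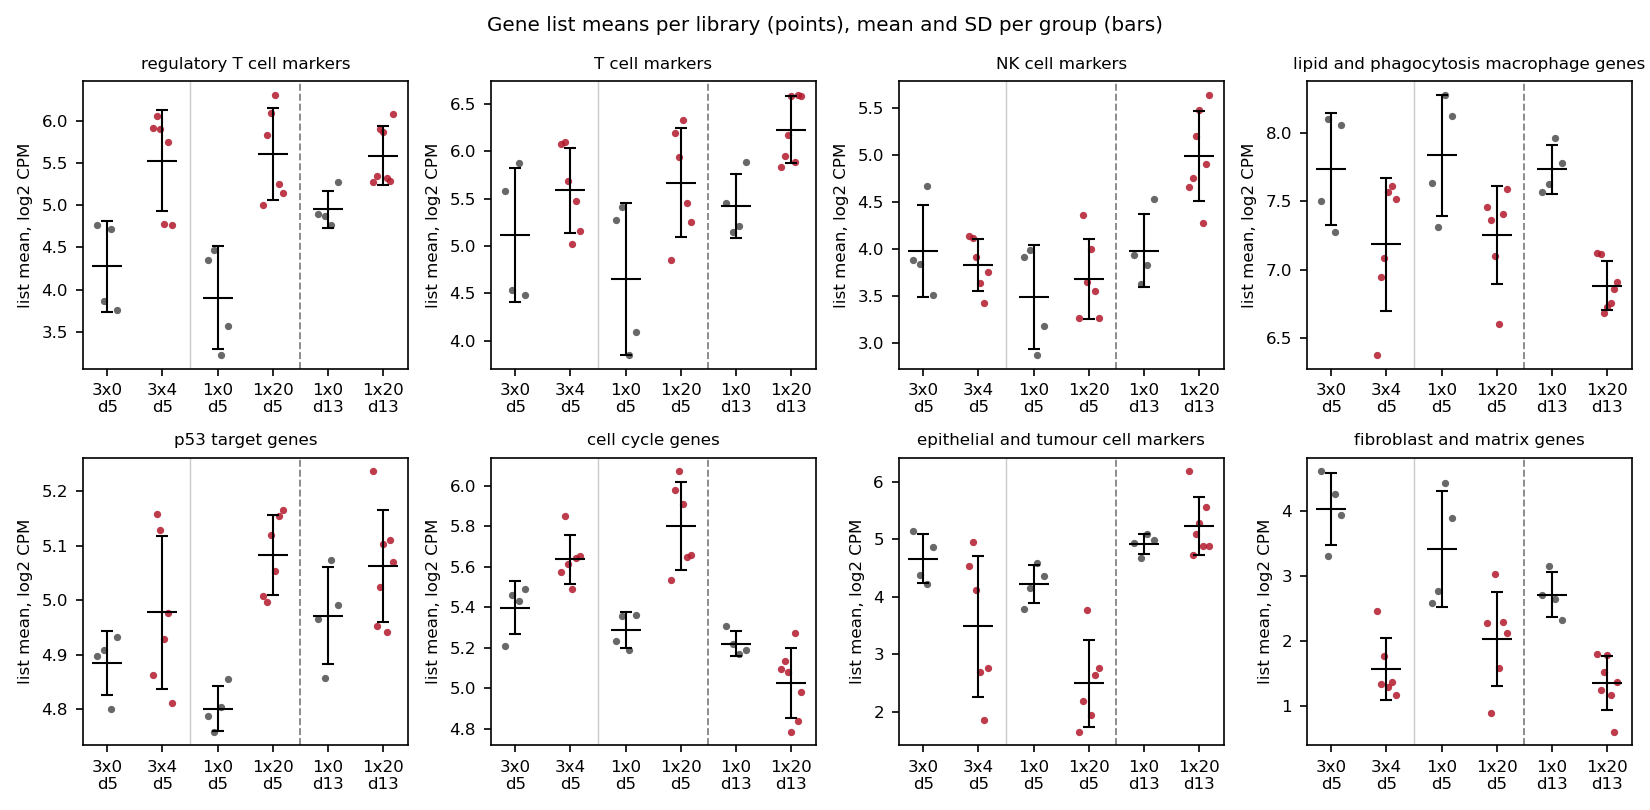
Mean log2 CPM of the members of 8 gene lists in each library (points), with mean and SD per group (bars); irradiated groups are red and mock groups grey. Regulatory T cell markers are higher after both regimens at day 5 (median log2 fold changes 1.35 and 1.74), and lipid and phagocytosis genes of macrophages lower after 1x20Gy at day 13 (median -0.80).

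The regimens were compared in 2 ways at day 5. The difference of their responses, each against its own mock, was called for 0 of 12021 genes by edgeR, with 714 at an unadjusted p below 0.05, 1 gene by DESeq2 and 2 by limma voom. Mast cell, basophil and eosinophil markers had a median difference of -1.75, that is, a smaller response to 3x4Gy, with 0 of 8 members called (5 lower adjusted over the list alone; camera adjusted p = 0.00015, adjusted p = 0.44 with an estimated correlation). Most of this gap lies between the mocks: the list mean was 2.25 ± 0.73 log2 CPM in 3x0Gy and 1.25 ± 0.37 in 1x0Gy (n = 4 each), against 2.75 ± 0.73 after 3x4Gy and 3.01 ± 0.32 after 1x20Gy (n = 6 each), and the irradiated groups did not differ as a list (median -0.16, camera adjusted p = 0.41). Plasma cell genes had a median difference of -1.23 with 0 of 10 called (3 lower adjusted over the list alone; camera adjusted p = 0.00015, adjusted p = 0.44 with an estimated correlation). Their list mean was 4.96 ± 0.81 log2 CPM in 3x0Gy and 4.25 ± 0.62 in 1x0Gy, against 3.41 ± 0.45 after 3x4Gy and 4.06 ± 0.28 after 1x20Gy. Camera called 7 of 33 lists for this difference, against 0 by fry.

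Compared directly, 3x4Gy differed from 1x20Gy in 3 of 12021 genes, with 826 at an unadjusted p below 0.05. Fgb, fibrinogen beta, was higher after 3x4Gy (log2 fold change 4.16, SE 0.73, adjusted p = 0.04; 3.52 without 3x4Gy library 2), as was the uroplakin gene Upk3a (4.80, SE 0.84, adjusted p = 0.04), chosen after its values were seen. The macrophage and monocyte transglutaminase F13a1 was lower, at 6.47 ± 1.99 CPM against 22.1 ± 5.41 CPM (n = 6 each; log2 fold change -1.77, SE 0.30, edgeR adjusted p = 0.04). Leaving out any 1 of the 12 libraries changed the count of 3 by over 1.5 times, to between 0 and 5 genes, and without any 1 of the 6 1x20Gy libraries none of the 3 was called. All 3 calls also ended with the epithelial and fibroblast mean as a covariate and with the share of reads outside annotated genes as one. DESeq2 called 13 genes and limma voom 1. Cdkn1a (0.12, SE 0.16, adjusted p = 0.94) and Foxp3 (0.11, SE 0.35, adjusted p = 0.98) were not called.

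Type 2 conventional dendritic cell markers were lower after 3x4Gy than after 1x20Gy as a list, with a median of -0.40 and 0 of 8 members called (2 lower adjusted over the list alone). This was the list that camera called with both correlations (adjusted p = 3.1e-05, adjusted p = 0.023 with an estimated correlation, fry adjusted p = 0.013). The mock groups differed in the same direction, with 8 of 8 members lower in 3x0Gy than in 1x0Gy, a median of -0.15 and 0 called (0 adjusted over the list alone; camera adjusted p = 0.036, adjusted p = 0.34 with an estimated correlation). The difference of the responses was not called for this list (median -0.18, camera adjusted p = 0.47), so the gap is not shown to be an effect of the regimen. Type I interferon response genes had 25 of 26 members with a positive sign and a median of 0.31, with 0 called (7 higher adjusted over the list alone; camera adjusted p = 7.5e-13, adjusted p = 0.21 with an estimated correlation). In the mock groups 23 of 26 were also positive, with a median of 0.22 and 0 called (0 adjusted over the list alone; camera adjusted p = 0.003, adjusted p = 0.66 with an estimated correlation), and the difference of the responses was not called (median 0.10, camera adjusted p = 0.091). Epithelial and tumour cell markers had a median of 1.60 and 0 of 15 called (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.4e-08, adjusted p = 0.44 with an estimated correlation). For these the mock groups had a median of 0.52 and 13 of 15 positive, with 0 called (0 adjusted over the list alone; camera adjusted p = 0.025, adjusted p = 0.66 with an estimated correlation). Erythroid genes were 1.00 log2 CPM lower per library after 3x4Gy (1.91 ± 0.72 against 2.91 ± 0.39, n = 6 each; exact p = 0.0152, adjusted 0.0421), and 0.43 lower in 3x0Gy than in 1x0Gy (n = 4 each; exact p = 0.286, adjusted 0.357).

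The day 5 responses were also compared across genes, which are not independent replicates. Log2 fold changes of 3x4Gy and 1x20Gy against their mocks had a Pearson r of 0.784 and a Spearman rho of 0.613 over 12021 genes, with no library in common. In 99 regroupings of irradiated and mock labels the highest values were 0.464 and 0.359. Both regimens raised 202 genes where 22.9 would be shared by chance and lowered 412 where 41.6 would be, and 0 genes were called in opposite directions by edgeR. Inhba, F10, Chac1, Foxp3, Il2ra and Cdkn1a were among the genes that rose after both. Day 5 and day 13 responses to 1x20Gy had an r of 0.506 and a rho of 0.388 over 10962 genes. The regroupings reached 0.492 and 0.475, so that the r was above all 99 and the rho below 2 of them.

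**Figure D4:**
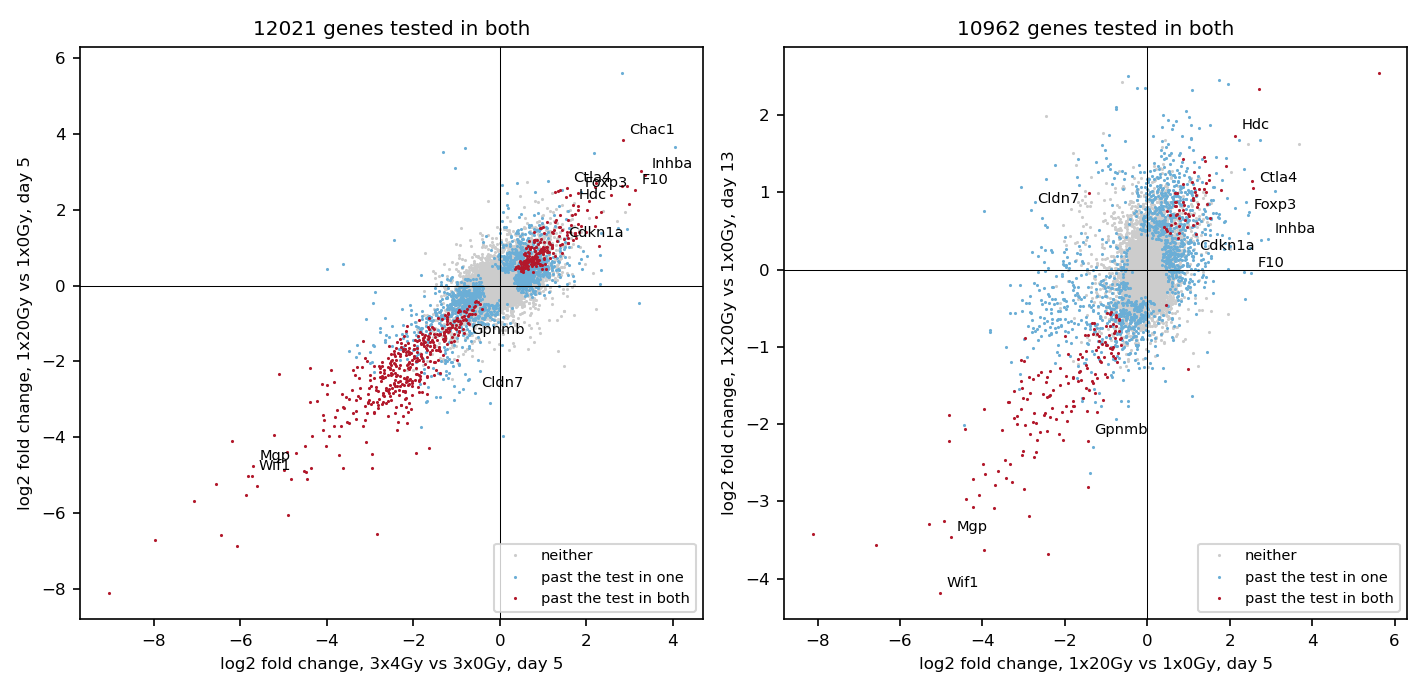
Log2 fold changes of 3x4Gy against 1x20Gy at day 5, each relative to its own mock (left), and of 1x20Gy at day 5 against day 13 (right), 1 point per gene; red genes passed the test in both comparisons and blue genes in 1. Over all genes tested in both comparisons, called or not, Pearson r was 0.784 on the left and 0.506 on the right. A gene with no counts in a group, such as Dcpp3, is drawn at a fitted value that depends on the fit.

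At day 13 after 1x20Gy, members of the T cell, cytotoxic and NK cell lists were higher and members of the macrophage lists lower than in the 1x0Gy mocks. Eomes, a transcription factor of cytotoxic and NK cells, rose from 11.8 ± 4.85 CPM (SD, n = 4) to 31.7 ± 6.13 CPM (n = 7), a log2 fold change of 1.43 (SE 0.24, adjusted p = 0.0025). Cd3e, a chain of the T cell receptor complex, rose from 31.2 ± 8.89 to 66.0 ± 16.3 CPM (log2 fold change 1.09, SE 0.21, adjusted p = 0.006). Gpnmb, a glycoprotein of lipid-laden macrophages, fell from 123 ± 38.3 to 26.6 ± 6.96 CPM (log2 fold change -2.21, SE 0.21, adjusted p = 6.4e-05; chromosome 6, 49036546 to 49070929, plus strand). The insulin-like growth factor gene Igf1 fell from 41.5 ± 9.76 to 5.87 ± 2.56 CPM (log2 fold change -2.81, SE 0.27, adjusted p = 6.4e-05).

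Here 467 genes were higher and 424 lower of 11071 tested, 194 and 176 of them by at least 2-fold. Of 19 T cell markers 11 rose and 8 were not called (18 rose adjusted over the list alone), including Cd2 (1.23, SE 0.26) and the costimulatory receptor Cd28 (1.13, SE 0.20). The list had a median of 0.82 (camera adjusted p = 2.4e-13, adjusted p = 0.13 with an estimated correlation). Cytotoxic lymphocyte genes had 9 of 18 higher (15 higher and 1 lower adjusted over the list alone), with the transcription factor Tbx21 (1.51, SE 0.28) and the receptor Klrc1 (1.18, SE 0.24). Members had a median of 0.91 (camera adjusted p = 5.5e-11, adjusted p = 0.13 with an estimated correlation). Cd8a was at 184 ± 71.0 against 122 ± 33.1 CPM (adjusted p = 0.14). NK cell markers had 7 of 12 higher (8 adjusted over the list alone; median 1.21, camera adjusted p = 2.7e-07, adjusted p = 0.15 with an estimated correlation). They included Ncr1, the NK receptor NKp46 (20.2 ± 11.3 against 5.01 ± 3.04 CPM; log2 fold change 2.00, SE 0.43, adjusted p = 0.01, and 0.053 without 1x0Gy library 3), and Klra4 (1.71, SE 0.32), which has close paralogs. Exhaustion and activation genes had 5 of 12 higher (5 adjusted over the list alone), with Rgs16 at 1.32 (SE 0.24) and Ctla4 at 1.06 (SE 0.21). The list median was 0.47 (camera adjusted p = 0.00072, adjusted p = 0.18 with an estimated correlation). Regulatory T cell markers had 3 of 9 higher (8 adjusted over the list alone; median 0.71, camera adjusted p = 2.6e-05, adjusted p = 0.18 with an estimated correlation), and Foxp3 was at 11.7 ± 4.69 against 7.22 ± 1.63 CPM (adjusted p = 0.17).

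Lipid and phagocytosis genes of macrophages fell in 10 of 14 cases (13 adjusted over the list alone), with a median of -0.80. For this list the call held with both correlations (camera adjusted p = 5.2e-17, adjusted p = 0.042 with an estimated correlation, fry adjusted p = 0.00061). Besides Gpnmb, Trem2 fell by 1.24 (SE 0.21), the lipoprotein lipase gene Lpl by 0.86 (SE 0.13) and Ctsd by 0.77 (SE 0.11). Macrophage genes had 7 of 18 lower and 1 higher (13 and 1 adjusted over the list alone), including the lysozyme gene Lyz2 (-1.21, SE 0.19) and apolipoprotein gene Apoe (-0.95, SE 0.13). The list had a median of -0.59 (camera adjusted p = 6.2e-10, adjusted p = 0.10 with an estimated correlation). The elastase gene Mmp12 fell by 1.63 (SE 0.22) in the suppressive myeloid list, the 1 of 12 members called (1 lower adjusted over the list alone). Members had a median of -0.26 (camera adjusted p = 0.038, adjusted p = 0.13 with an estimated correlation). Hypoxia and glycolysis genes had 8 of 14 lower (9 adjusted over the list alone), with the mitophagy gene Bnip3 (-1.60, SE 0.25) and the glucose transporter gene Slc2a1 (-0.78, SE 0.15). The list median was -0.53 (camera adjusted p = 6.3e-08, adjusted p = 0.091 with an estimated correlation). Type I interferon response genes had 0 of 26 called (0 adjusted over the list alone; median -0.35, camera adjusted p = 0.0066, adjusted p = 0.33 with an estimated correlation). Immediate early and heat shock genes had 1 of 14 higher and 2 lower (1 and 2 adjusted over the list alone), with Egr1 at -1.01 (SE 0.14). The list had a median of -0.15 (camera adjusted p = 0.023, adjusted p = 0.13 with an estimated correlation).

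Neutrophil genes had 5 of 11 higher and 1 lower (7 and 1 adjusted over the list alone; median 1.30, camera adjusted p = 3.7e-05, adjusted p = 0.13 with an estimated correlation). Hdc rose by 1.73 (SE 0.25), the calcium-binding protein gene S100a9 by 1.68 (SE 0.35) and the gelatinase gene Mmp9 by 2.34 (SE 0.37), and by 3.05 without 1x0Gy library 4. Plasmacytoid dendritic cell markers had 3 of 8 higher (5 higher and 2 lower adjusted over the list alone), with the lectin gene Siglech (1.47, SE 0.26) and the chemokine receptor gene Ccr9 (1.23, SE 0.27). Members had a median of 0.74 (camera adjusted p = 0.017, adjusted p = 0.19 with an estimated correlation). Of 20 p53 targets 1 rose (1 adjusted over the list alone; camera adjusted p = 0.30), and Cdkn1a was at 214 ± 33.1 against 190 ± 58.5 CPM (adjusted p = 0.60). Cell cycle genes had 1 of 27 lower (1 adjusted over the list alone; median -0.17, camera adjusted p = 0.072). The interferon gamma-induced chemokine gene Cxcl9 was at 308 ± 71.8 against 418 ± 62.0 CPM (adjusted p = 0.13).

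Markers of other tumour cells went different ways at day 13. Epithelial and tumour cell markers had 4 of 14 higher and 1 lower (7 and 1 adjusted over the list alone; median 0.63, camera adjusted p = 0.072), with the tight junction gene Cldn3 at 1.67 (SE 0.34) and the basal keratin Krt14 at -1.53 (SE 0.27). Another basal keratin, Krt15, fell by 2.63 (SE 0.32), and the adaptor gene Grb14 (2.89, SE 0.57) and Upk3a (2.51, SE 0.52) rose. Per library the epithelial median was 6.05 ± 0.73 log2 CPM (n = 7) against 4.6 ± 0.23 (n = 4; exact p = 0.00909, adjusted 0.0298). The mean of the same list was 5.23 ± 0.51 against 4.93 ± 0.17 (exact p = 0.303), so the difference of 1.45 fell to 0.308 and its call ended. Fibroblast and matrix genes had 4 of 6 lower (4 adjusted over the list alone; median -1.55, camera adjusted p = 1.2e-05, adjusted p = 0.091 with an estimated correlation), with Postn (-2.40, SE 0.41) and Sparc (-1.84, SE 0.35). Wif1 fell by 4.19 (SE 0.39) and Mgp by 3.46 (SE 0.53), and by 4.25 without 1x20Gy library 5. Endothelial markers had 1 of 4 higher (2 adjusted over the list alone; camera adjusted p = 0.017, adjusted p = 0.13 with an estimated correlation).

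The day 13 count fell to 588 without 1x0Gy library 2 and to 306 without library 3, and was 514 without mock libraries 1 and 2, whose RP23-81C12.3 shares were the highest of the 4. Limma voom called 1395 genes, and 290 passed an adjusted p of 0.01. Scaling by library size gave 222 higher and 1311 lower genes, with the median of all genes moved by -0.23. Without mock libraries 1 and 2, 13 of 43 followed calls ended, among them Cd2, Klrc1, Rgs16, Ncr1, Klra4, S100a9, Cldn3 and Upk3a, and those of Eomes, Tbx21, Cd3e, Gpnmb, Igf1, Trem2, Apoe, Lyz2 and Bnip3 were kept. Leaving out only 1x0Gy library 3 ended 7 of the 43, library 1 ended 4 and library 2 ended 3. In 1 fit of all 31 libraries 12 of the 43 ended, among them Cd3e, Cd28, Ctla4, Klrc1, S100a9, Lpl, Siglech and Ccr9.

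The last comparison asked whether the response to 1x20Gy at day 13 differed from that at day 5, with day and experiment confounded. Cell cycle genes were lower in the later response, with a median difference of log2 fold changes of -0.68 and 26 of 27 members negative. Of these, 4 were called (13 adjusted over the list alone): Plk1 (-1.31, SE 0.25), Birc5 (-1.03, SE 0.22), Ube2c (-1.29, SE 0.30) and the cyclin gene Ccnb1 (-1.22, SE 0.26). The list was called with both correlations (camera adjusted p = 2.7e-16, adjusted p = 0.014 with an estimated correlation, fry adjusted p = 0.00086). Epithelial and tumour cell markers were higher in the later response, with a median of 2.21 and 1 of 15 called (13 adjusted over the list alone; camera adjusted p = 1.9e-13, adjusted p = 0.24 with an estimated correlation), the tight junction gene Cldn7 (3.63, SE 0.80).

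Across all genes 25 differences were positive and 26 negative of 12061, with 1499 at an unadjusted p below 0.05. The signalling inhibitor Spry2 had the smallest adjusted p (2.42, SE 0.37, adjusted p = 0.0035). Emp2 (2.43, SE 0.57) and Bst2 (1.40, SE 0.29) were also positive, and Inhba (-2.52, SE 0.55), F10 (-2.54, SE 0.53), Mmp12 (-2.70, SE 0.61) and Cxcl2 (-1.87, SE 0.44) negative. Regulatory T cell markers had a median of -1.0 and 0 of 9 called (5 lower adjusted over the list alone; camera adjusted p = 5.2e-06, adjusted p = 0.26 with an estimated correlation), and NK cell markers a median of 0.93 and 0 of 12 called (0 adjusted over the list alone; camera adjusted p = 0.0017, adjusted p = 0.34 with an estimated correlation). Foxp3 (-1.71, SE 0.58, adjusted p = 0.18), Ncr1 (1.63, SE 0.62, adjusted p = 0.24) and Cdkn1a (-0.92, SE 0.25, adjusted p = 0.091) were not called, so their different outcomes on the 2 days are not shown to differ. The count of 51 ran from 1 to 110 when 1 library was left out, with 19 of the 21 libraries moving it by over 1.5 times (110 without 1x20Gy library 5 of day 13), and none of the 12 calls named here held in each of those fits and alternatives. DESeq2 called 193 genes and limma voom 497, and 11 of 18 alternatives moved the count by over 1.5 times, to between 1 and 497.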

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

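Tests chosen only after their result was seen were those on the share of reads outside annotated genes in the 3 comparisons with mocks and the count of epithelial markers at day 13; those on the cell cycle list were written when counts of called genes, but not list medians, had been seen.

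Regrouping the libraries at random asked whether chance could give as many called genes. For 3x4Gy against 3x0Gy the real 1477 genes stood against at most 517 in the other splits. Of the 100 splits 1, the real one, gave as many, which makes chance an unlikely source of the count. The split with 517 put the 4 mock libraries together with 2 irradiated ones. For 1x20Gy against 1x0Gy the real 1028 genes at day 5 stood against at most 251 (1 of 100 splits). The real 891 at day 13 stood against at most 124 (1 of 100 splits), and chance is unlikely for both. Regrouping cannot test a difference in handling that goes with a whole group. For the difference of the regimens' responses edgeR called 0 genes (714 at an unadjusted p below 0.05), DESeq2 1 and limma voom 2. For the mock groups edgeR called 0 genes (667 at an unadjusted p below 0.05), DESeq2 1 and limma voom 0. Every split has at least 0 called genes, so the results of 100 of 100 and 35 of 35 splits were fixed in advance and decide nothing. The highest other counts were 17 and 36. For 3x4Gy against 1x20Gy (3 genes, highest other 49, 5 of 100 splits) chance is not excluded. For the 1x20Gy response at day 13 against day 5 (51 genes, highest other 492, 5 of 100 splits) the splits decide nothing, because irradiated and mock labels changed places within a day, which lets the irradiation effect into them. What made single splits of the other comparisons call more genes than the real one was not tested, and a structure of the samples is possible.

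The first pattern is the set of 622 genes outside the epithelial and fibroblast lists that were at least 2-fold lower after irradiation at day 5. Lower depth is not decided by thinning all libraries to 2641229 gene counts, which left the fold changes at a median ratio of 1 (quartiles 0.948 and 1.06). Thinning keeps each gene's expected share of a library, so a ratio near 1 was likely either way. Less RNA from epithelial and stromal cells, which the CD45.2 gate should remove, remains a candidate explanation: within groups the genes followed the mean of both lists across 20 libraries with a median correlation of 0.507 (quartiles 0.153 and 0.701), against -0.0304 for other genes, and of the lists' genes Epcam averaged 107 CPM and Sparc 51.1 CPM in 3x0Gy mocks. At day 13 a loss of epithelial RNA was not seen: 4 epithelial markers were called higher and 1 lower. The list mean per library was 5.23 ± 0.51 log2 CPM after 1x20Gy (SD, n = 7) against 4.93 ± 0.17 in mocks (n = 4). The list was not called by camera, and the call of Cldn3 ended without mock libraries 1 and 2. The count of 4 therefore does not decide the question. For the stromal part a fall was seen at day 13. The median of the fibroblast and matrix genes per library was 1.44 ± 0.42 log2 CPM after 1x20Gy (n = 7) against 2.80 ± 0.44 in mocks (n = 4, exact permutation p = 0.00303, adjusted 0.0238). Lower expression within leukocytes stays open and was not tested apart from a loss of epithelial and stromal RNA.

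The second pattern is the higher share of reads outside annotated genes in irradiated groups, with means of 24.1% after 3x4Gy and, after 1x20Gy, 23.5% at day 5 and 25.8% at day 13. These reads are no part of the gene comparisons. None of the 3 differences held after adjustment (adjusted p = 0.112, 0.164 and 0.167), and without 3x0Gy library 2 the first difference falls to 4.57 percentage points (exact p = 0.0595). With the share as a covariate, the fold changes of called genes kept a median ratio of 0.908 (quartiles 0.743 and 1.04) for 3x4Gy, 0.976 (0.878 and 1.08) for 1x20Gy at day 5 and 1.07 (0.917 and 1.24) at day 13. This argues against the share as the whole source of the changes, though fewer genes were called with it at day 5 (667 and 737) and 1179 at day 13. In the calls that ended, the median ratio was 0.788 (0.638 and 0.929), 0.883 (0.78 and 0.976) and 0.863 (0.762 and 0.976) in that order, and standard errors were 1.18, 1.15 and 1.3 times as large. Kept calls had ratios of 1.02, 1.04 and 1.18, with standard errors 1.19, 1.15 and 1.25 times as large. Both sets were chosen by whether the call ended, so their ratios do not show why calls ended. What raised the share, in biology or in library preparation, was not tested.

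The third pattern is the cell cycle list, lower in the day 13 than in the day 5 response to 1x20Gy with a median difference of -0.68. The day 13 mock libraries 1 and 2, which had the highest RP23-81C12.3 shares, are argued against as its source by a median of -0.652 without them, and the share of reads outside genes by a median of -0.692 with it as a covariate. Over 38 settings the median lay between -0.82 and -0.60. A difference in proliferation between the days may remain, but day and experiment code are confounded, so it stays a hypothesis.

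That difference between days was itself tested, and 51 genes passed: Spry2 (2.42), Cldn7 (3.63), Emp2 (2.43), Bst2 (1.40), Inhba (-2.52), F10 (-2.54), Mmp12 (-2.70), Cxcl2 (-1.87), Plk1 (-1.31), Birc5 (-1.03), Ube2c (-1.29) and Ccnb1 (-1.22) among those named, on the log2 scale. The count ran from 1 to 110 with 1 library left out, and 0 of these 12 calls held in all settings and left-out libraries.

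Single libraries stood far from the others of their group in 30 of 592 tests, as many as the 30 that chance gives, so each of these values alone may be chance. They came from 16 libraries. Total gene counts of 1x0Gy library 1 at day 5 were 7541144 (others 5647013 to 5850310). Reads in 3x0Gy library 2 were assigned to genes in 68.2% of cases (others 56.2% to 57.2%), and this library lay apart on other measures too. Its share of reads outside genes was 5.66% (others 16.5% to 21.5%), its mitochondrial share 0.611% (others 2.89% to 3.96%) and its RP23-81C12.3 share 0.148% (others 2.55% to 4.71%). It correlated with the other 3x0Gy libraries at 0.892 to 0.928, against 0.964 to 0.977 among them. Without it 1151 genes were called for 3x4Gy against 3x0Gy. By correlation 3x4Gy library 1 also lay apart, at 0.914 to 0.939 with its replicates against 0.95 to 0.984 among them, and without it 1326 genes were called. These measures were brought together after they were seen, and why either library differs was not tested. Immunoglobulin counts took 0.13% in 3x0Gy library 1 (others 0.0417% to 0.0489%) and 0.0822% in 1x0Gy library 4 at day 5 (others 0.0171% to 0.0271%).

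Among list means in log2 CPM, B cell markers were 2.35 in 1x20Gy library 6 of day 13 (others 2.75 to 3.00) and MHC class II genes 8.04 in 1x0Gy library 1 of day 13 (others 8.17 to 8.19). Suppressive myeloid genes were 4.68 in 3x4Gy library 6 (others 3.59 to 3.92) and 4.6 in 1x20Gy library 2 of day 5 (others 4.10 to 4.24). Hypoxia and glycolysis genes were 5.66 in that 3x4Gy library (others 5.31 to 5.43) and 5.72 in that 1x20Gy library (others 5.07 to 5.27). Adipose and mammary gland genes were 2.23 in 1x20Gy library 3 of day 5 (others 0.84 to 1.21).

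Among genes in log2 CPM, 3x4Gy library 1 stood apart for Pf4 (2.39, others 3.58 to 4.26) and Mki67 (8.44, others 7.15 to 7.59), library 4 for H19 (-1.19, others 0.15 to 0.93) and library 6 for Smoc1 (-0.62, others 0.54 to 1.09). Of the mocks, 3x0Gy library 1 stood apart for F13a1 (3.06, others 4.01 to 4.04) and Retnla (5.20, others 7.62 to 7.85), and 1x0Gy library 3 of day 5 for Egln3 (4.27, others 3.54 to 3.6). After 1x20Gy at day 5, library 2 stood apart for Il1f9 (6.07, others 0.97 to 2.52) and Mmp12 (7.85, others 6.17 to 6.76), library 3 for Ptprc (9.21, others 9.76 to 9.94) and Birc5 (8.42, others 7.52 to 7.85), and library 4 for Ctsd (8.77, others 9.58 to 9.77) and Mdm2 (8.06, others 8.26 to 8.37). At day 13, 1x20Gy library 5 stood apart for F10 (1.73, others 3.40 to 3.86) and Smoc1 (3.43, others 0.07 to 1.41), 1x0Gy library 4 for Sparc (4.26, others 4.77 to 4.84), Mmp9 (2.27, others 0.64 to 0.83) and Klra4 (3.31, others 2.41 to 2.53), and 1x0Gy library 3 for Ccr9 (2.92, others 4.48 to 4.76).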

How the results depend on the processing

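The alternatives chosen after the data were seen were the covariates, counting without RP23-81C12.3 and mitochondrial rRNA genes, day 13 without mock libraries 1 and 2, and the epithelial level per library as a list mean in place of a median; the cause of a change was not tested unless an alternative's construction shows it. Alternatives, apart from leaving out a library, left the count within 1.5 times in 13 of 18 settings for 3x4Gy against 3x0Gy (1477 genes), 13 of 18 for 1x20Gy against 1x0Gy at day 5 (1028) and 14 of 19 at day 13 (891). The exceptions for 3x4Gy were 702 genes with the libraries of the compared groups alone, 667 with the share of reads outside genes as a covariate, 278 with the epithelial and fibroblast mean as a covariate, 740 with a minimum 2-fold change and 665 at an adjusted p below 0.01. At day 5 after 1x20Gy they were 625 with the stricter filter, which tests fewer genes, 1957 by limma voom, 204 with the epithelial and fibroblast mean, 630 with a minimum 2-fold change and 425 below 0.01. At day 13 they were 1533 by library size, 1395 by limma voom, 514 without mock libraries 1 and 2, 370 with a minimum 2-fold change and 290 below 0.01.

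Of the smaller counts, those of 3 and 51 moved in 8 and 11 of 18 settings and both counts of 0 in 3 of 18. For the difference of the regimens' responses (0) there was 1 gene with no filter, 1 by DESeq2 and 2 by limma voom. For 3x4Gy against 1x20Gy (3) there were 5 with no filter, 0 with the stricter filter, 13 by DESeq2, 1 by limma voom, 1 with the compared groups alone, 0 with either covariate and 0 below 0.01. For the mock groups (0) there was 1 with no filter, 1 by DESeq2 and 1 in a fit of all 31 libraries. For the 1x20Gy response at day 13 against day 5 (51) there were 5 with upper quartile scaling, 85 with no filter, 31 with the stricter filter, 193 by DESeq2, 497 by limma voom, 237 with the compared groups alone, 16 with the replicate block, 6 without RP23-81C12.3 and mitochondrial rRNA genes, 19 with the epithelial and fibroblast mean, 2 without the day 13 mock libraries and 1 below 0.01.

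Leaving out 1 library at a time gave 1132 to 1815 genes for 3x4Gy, 556 to 1024 for 1x20Gy at day 5 (582 without 1x0Gy library 3, 556 without library 4), 306 to 1264 at day 13 (588 without 1x0Gy library 2, 306 without library 3), 0 to 1 for the difference of the regimens, 0 to 5 for 3x4Gy against 1x20Gy, 0 to 1 for the mock groups and 1 to 110 for the difference between days. With title numbers as a replicate block the counts were 1223, 876 and 1064 for the comparisons with mocks in that order, and 4 for 3x4Gy against 1x20Gy. The block ended 1 of 48, 4 of 45, 0 of 43 and 1 of 3 followed calls in the same order. Of all calls made without it, 1117 of 1477, 742 of 1028 and 727 of 891 were kept in the comparisons with mocks. Nothing in the labels says that the numbers pair animals. Same-number libraries had a residual correlation above 0.1 in 2 of 4, 2 of 4 and 3 of 4 pairs, and the same number was the most correlated partner in 3 of 4, 2 of 4 and 3 of 4. Between 3x4Gy and 1x20Gy the same number was the most correlated partner in 0 of 6 pairs, and between the mock groups in 1 of 4. The hint that some numbers go together is thus limited to irradiated against mock groups and short of every pair. How often chance gives such partners was not tested, so pairing is not excluded and the block stays a check.

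Camera called 13, 17 and 15 lists in the comparisons with mocks at the preset correlation, 0, 0 and 1 with an estimated one, and fry called 14, 12 and 16. For the difference of the regimens it called 7 and then 0 (fry 0), for 3x4Gy against 1x20Gy 10 and then 1 (fry 1), for the mock groups 17 and then 0 (fry 0), and for the difference between days 10 and then 1 (fry 1).

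No called gene among those followed reversed its direction. Of 48 called genes for 3x4Gy 20 kept their call in every setting and left-out library, of 45 for 1x20Gy at day 5 21, of 43 at day 13 22, and of 3 and 12 in the last comparisons 0. Genes that were not called and changed sign were Gzmb (0.0737 by limma voom, 0.26 with the share of reads outside genes) and Ifng (0.34 with that share) after 3x4Gy, and Ptprc (-0.0218 by library size, -0.22 with that share), Cxcl10 (0.17 with that share, and -0.141 to 0.044 with 1 library left out, positive without 1x20Gy library 4 or 1x0Gy library 3) and Cd8a (-0.0656 to 0.525 with 1 library left out, negative without 1x0Gy library 3 or 4) after 1x20Gy at day 5. The others were Cdkn1a at day 13 (-0.0441 by library size, -0.0030 with that share) and Foxp3 between the regimens (-0.0882 with the epithelial and fibroblast mean, -0.0916 to 0.326 with 1 library left out, negative without 3x4Gy library 1). Thinned to 2641229 counts per library, 1241 genes were called after 3x4Gy and 735 after 1x20Gy at day 5. With 4 mock libraries per group, 2-fold changes were recovered in 31% to 67% of simulated cases and 4-fold changes in 83% to 95%. Many changes of 2-fold and some of 4-fold may thus have gone undetected, as may smaller ones. Apart from this, the calls depended on the model. At day 5 after 1x20Gy they ran from 204 with the epithelial and fibroblast mean as a covariate to 1957 by limma voom.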

Other observations

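The tests of regulatory T cell against T cell genes were chosen after the list results were seen; the test of Lcn2 was written before its correlations were computed.

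Genes that changed after both regimens at day 5 but stand in none of the lists included Chac1, Inhba, Wif1, Mgp, Peg3 and Smoc1, and 3x4Gy at day 5 and 1x20Gy at day 13, which share no library, had 59 genes higher in both (24.6 by chance) and 192 lower in both (28.0 by chance). For those responses the Pearson r was 0.515 and the Spearman rho 0.358 across 10962 genes, which are not independent replicates, and 6 genes were called in opposite directions. Smoc1 fell by 4.49 after 3x4Gy, by 4.24 after 1x20Gy at day 5 and by 3.07 at day 13, on the log2 scale, and by 4.97 without 1x20Gy library 2 of day 5 and 3.76 without 1x20Gy library 5 of day 13.

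A hypothesis is that regulatory T cell genes rose more than T cell genes in general. The mean of the regulatory list minus that of the T cell list was -0.05 ± 0.27 log2 CPM after 3x4Gy (SD, n = 6) and -0.84 ± 0.21 in its mocks (n = 4; exact permutation p = 0.00476, the smallest of 210 splits, adjusted 0.00714), higher in 6 of 6 libraries than in all mocks. After 1x20Gy at day 5 it was -0.06 ± 0.20 (n = 6) against -0.75 ± 0.21 (n = 4; exact p = 0.00476), again in 6 of 6. At day 13 the difference of means was -0.17 (exact p = 0.388), with 1 of 7 libraries above all mocks, so a larger rise was not seen there. A larger share of regulatory cells among T cells, or more of these transcripts per cell, may account for the day 5 values.

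Lcn2 fell at day 5 while other neutrophil genes such as Hdc rose. A hypothesis is that its counts come from epithelial cells, which also express it and which the CD45.2 gate should remove. Within groups, Lcn2 followed the epithelial list over 31 libraries (Pearson r = 0.648, permutation p = 0.00145; Spearman rho = 0.676, permutation p = 0.00052; r = 0.638 without the 2 libraries farthest from the median), and not the neutrophil list (r = -0.0433, permutation p = 0.859; rho = -0.0464, permutation p = 0.837; r = -0.303 without the 2 farthest), with 100000 resamples within groups. These 2 relations were the ones computed, and the result is consistent with an epithelial source without showing it.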
